A study of Mus musculus with 41 samples.

How the data were processed

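The series holds polyA RNA-seq of liver and liver tumour tissue of male C57BL/6 mice. The labels give 3 disease stages on a high-fat diet (HFD): a fatty liver called healthy (HFD control), NASH (steatohepatitis) and HCC (liver tumours). They also give livers called healthy in groups marked NC, a term the labels do not explain. Genotypes are named B6, MupHe, IgAkMup, CD8kMup, IgAkCLM and CD8kCLM, and these names were kept as given. Per the submitters' protocol, libraries were made with the TruSeq Stranded mRNA kit from 100 ng of RNA. RNA came from AllPrep columns, and for some livers from Trizol followed by RNeasy columns. Per the submitters' processing notes, STAR and Cuffdiff were named for the 29 HFD-fed samples, and STAR, HOMER and DESeq2 for the 12 NC samples, all with the mm10 genome. The notes give no versions and no roles of these tools.

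The values are regularized log2 (rlog) values, on a log2 scale, as the authors deposited them in 1 table of 24511 genes and 41 libraries. Such values are normalized for library size and shrunk toward each gene's mean where counts are low, so differences of weakly expressed genes can be understated. The program and version that made them, and whether all libraries were normalized together, are not given in the sources used here. The values ran from -2.3886 to 20.931, and 5599 genes stood at 0 in every library used. No counts were used, so the sequencing depth behind each value is unknown and no counting interval can be given.

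Columns were matched to samples by name. NC columns matched single samples. The other columns matched a group only, so their libraries carry the number that ends the column name, such as MupHe HCC 7. The names of 6 columns matched both CD8kMup NASH and CD8kCLM HFD control, and these 6 columns were not used. Those groups are therefore not analysed here, and 3 planned comparisons that need them were not run. The planned means over genotypes became means over the 2 genotypes left. In all, 35 libraries in 11 groups were used, with n = 3 per group except n = 4 in MupHe HCC and IgAkMup HCC. The labels do not say that replicates are separate animals, so every p-value measures the spread between these samples only.

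Column names also carry tags that the labels do not explain. SS N marks the B6 HFD control and IgAkMup NASH libraries, Tri N the IgAkCLM HFD control and MupHe NASH libraries, SS H all HCC libraries and Tri NC all NC libraries. Comparisons within HCC and within NC are therefore matched for the tag, and most others are not. For NASH against HFD control, results within Tri N and within SS N are given beside the others. For MupHe HCC against NASH and for HFD against NC, a group was exchanged for one whose tag shares the first part (SS N with SS H, Tri N with Tri NC). The groups then share SS or Tri and differ in the second part, which follows tumours (H), other HFD livers (N) and NC livers. H and N were also used to match columns to stages. IgAkMup HCC against NASH shares SS without an exchange. Whether libraries that share only the first part were handled alike is not known, and each exchange of a group also changes its genotype. The comparisons of IgAkCLM with B6 and of IgAkMup with MupHe NASH have no version within 1 tag. A fit with the tag as a term is not possible beside the groups, since each group carries a single tag.

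Genes with a mean of at least 3 over the libraries were kept, which left 12337. All 11 groups entered a single limma fit (limma 3.58.1 in R 4.3.3) with a mean per group, and contrasts were tested with eBayes and trend. P-values were adjusted by the method of Benjamini and Hochberg over all kept genes, with a threshold of 0.05, and all tests were two-sided unless named otherwise. The comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. After the column names and first results were seen, 3 comparisons were added, so that 16 were run. They were IgAkMup NASH against IgAkCLM HFD control, IgAkMup HCC against IgAkMup NASH, and the difference of the NASH contrasts. The last sets IgAkMup NASH minus IgAkCLM HFD control against MupHe NASH minus B6 HFD control.

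Of 38 gene lists written from general knowledge of liver, immune cells and liver cancer, 32 had at least 5 kept genes. These were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance. List members past 0.05 were counted over all kept genes and adjusted over the list alone. Igha, Cd8a, Cd8b1 and Plau were looked up first as the genes that the genotype names point to. Igha has no value in the table used here, so it was not tested. Cd8a, Cd8b1 and Plau were tested with exact two-sided permutation tests on the values of each pair of groups, adjusted over 36 tests.

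Genes named in the text followed a fixed rule. It takes from each comparison the 10 largest positive and 10 largest negative differences among genes past the threshold whose compared libraries do not overlap, or, in the means over genotypes, that move the same way in each genotype. It takes all genes of a comparison with at most 5 past the threshold, up to 4 members with the smallest adjusted p of each list past its test or described, and the 4 genes named above. Predicted genes and Riken clones were only counted, and a few genes that the rule names are not reported here. Gene positions come from GENCODE vM21 on GRCm38. Reads of near-identical paralogs, such as the Mup, Serpina, Cyp2c and Hbb families, may be shared between members, so single members of those families are uncertain.

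The alternatives were no filter, a filter at a mean of 5, median centring, quantile normalization, a fit of only the compared groups, no trend, robust eBayes, the replicate number as a block (NC groups only), and leaving out each library in turn. Added after the data were seen were weights per kind of library (limma arrayWeights, with a variance per disease stage and diet), control, NASH or HFD groups exchanged for ones of the same or a related tag, and leaving out 3 tumour libraries that lie apart on principal component 2 (MupHe HCC 3, IgAkMup HCC 5 and IgAkMup HCC 9). Splits of the same libraries into groups of the same sizes were counted, up to 100 per comparison with seed 1.

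The calls were tested on simulated data with 67, 67 and 66 genes shifted by 0.5, 1 and 2 log2 units. With equal spread in all groups, the mean NASH comparison recovered 61.2%, 86.6% and 100% of them, with 11 false among 176 calls. With each group's measured spread, that comparison gave 1 false among 171 calls, the NC comparisons gave 0 false among 133, 134 and 137 calls, and MupHe against B6 in NC recovered 26.9%, 74.6% and 98.5%. MupHe HCC and IgAkMup HCC vary more between libraries than the other groups, and where they enter the error rate was not held: HCC against NASH over both genotypes gave 58 false among 228 calls, IgAkMup against MupHe HCC gave 655 false among 815, and CD8kMup against MupHe HCC gave 106 false among 251. The weighted fit is therefore given beside the counts. On the same simulated data it lowered the false calls in these 3 comparisons to 20 among 188, 12 among 133 and 0 among 106. It did not hold the error rate throughout, with 35 false among 170 for MupHe HCC against NASH and 33 among 190 for HFD against NC, where the fit without weights gave 70 among 217 and 2 among 134. Its weights are set per disease stage and diet, so a difference in spread between tumour groups is not allowed for. No pair of libraries had identical values, and correlations between libraries of a group were at least 0.931. Figures were drawn with matplotlib 3.10.9.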

Results

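Gene expression was measured by RNA-seq in 35 libraries of mouse liver and liver tumour, from healthy livers of the NC groups through fatty liver and steatohepatitis (NASH) on a high-fat diet to hepatocellular carcinoma (HCC). All values are on a log2 scale, so a difference of 1 is a doubling, and errors of differences are standard errors. Groups held 3 libraries, except MupHe HCC and IgAkMup HCC with 4, and the sequencing depth was unknown. Adjusted p-values of genes are from limma and those of lists from camera.

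The first principal component held 47.9% of the variance and set the 11 tumour libraries, at 23.0 to 64.9, apart from the other groups. The second component held 12.6%. On it, MupHe HCC 3 (-29.1), IgAkMup HCC 5 (-28.4) and IgAkMup HCC 9 (-35.6) lay apart from the other tumours, which ranged from -5.12 to 24.7.

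**Figure D1:**
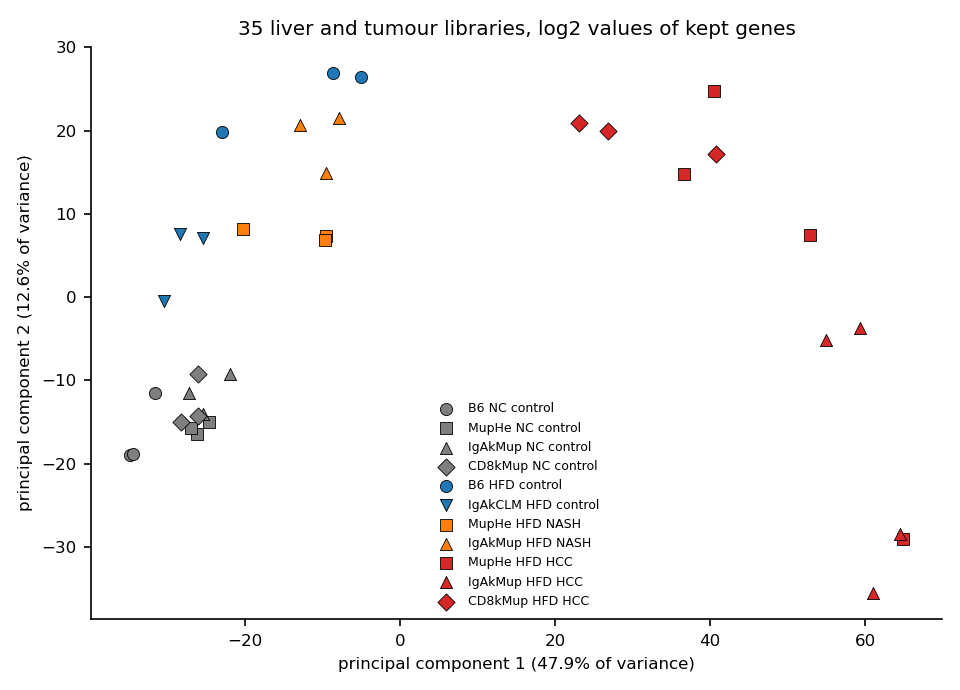
Each point is 1 of the 35 libraries on principal components 1 (47.9% of the variance) and 2 (12.6%) of the log2 values of the 12337 kept genes, with shapes for genotype and colours for stage. Tumour libraries stand at the right, from 23.0 to 64.9 on component 1.

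The genes that the genotype names point to were examined first. Cd8a, which encodes a chain of the CD8 coreceptor, did not differ detectably in libraries labelled CD8kMup. It stood at 3.81 ± 0.33 (SD, n = 3) in CD8kMup HCC and 3.93 ± 0.26 (n = 4) in MupHe HCC, exact p = 0.629, and at 3.80 ± 0.43 and 3.39 ± 0.30 in the NC groups (n = 3 each, exact p = 0.3). Cd8b1, which encodes the other CD8 chain, stood lower in CD8kMup HCC, at 1.82 ± 0.05 (n = 3) against 2.41 ± 0.25 (n = 4), exact p = 0.0286, the smallest that 3 against 4 libraries can give, and 0.36 after adjustment. In the NC groups it stood at 1.81 ± 0.08 and 2.03 ± 0.23 (n = 3 each, exact p = 0.2). Plau, which encodes urokinase, stood at 4.80 ± 0.06 in MupHe NC and 4.38 ± 0.17 in B6 NC (n = 3 each, exact p = 0.1, the smallest possible for 3 against 3, adjusted 0.36). Igha, the constant region of IgA heavy chains, has no value in the table used and is not analysed here.

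**Figure D2:**
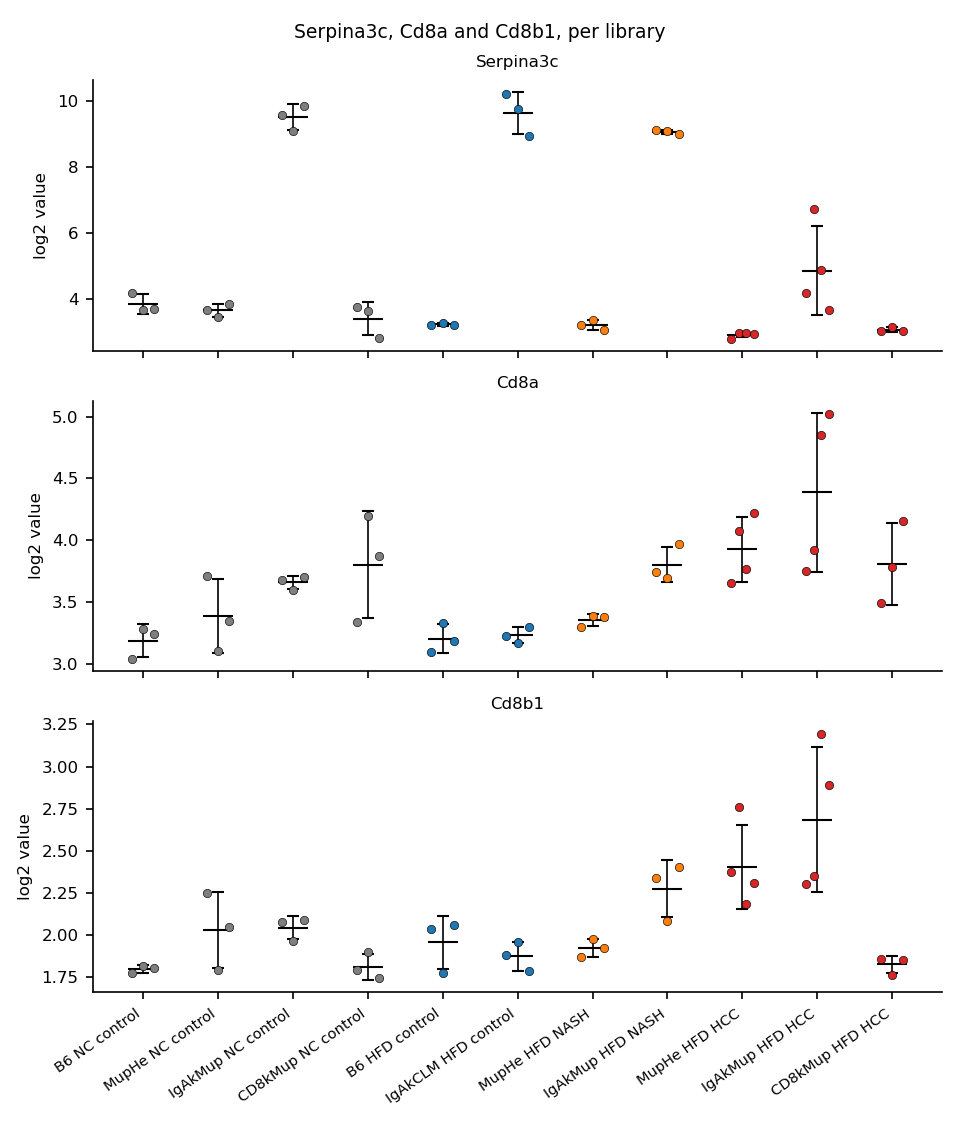
Points are log2 values of Serpina3c, Cd8a and Cd8b1 in each library, by group, with the group mean and SD as bars. Serpina3c stood at 9.06 to 9.62 on average in the NC, HFD control and NASH groups named IgAk, while Cd8a stood at 3.81 in CD8kMup HCC and 3.93 in MupHe HCC.

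Interferon-stimulated genes were higher in NASH livers than in fatty HFD control livers. All NASH genotype names hold Mup and no HFD control name does, so stage and that genotype cannot be told apart. In NC livers the interferon, recruited macrophage and cholangiocyte lists were also higher in MupHe than in B6. There no member passed over all genes, and no call held with an estimated correlation. Over MupHe and IgAkMup NASH against the B6 and IgAkCLM controls (n = 3 per group), Ifi44 rose by 1.82 ± 0.23, Irf7 by 1.36 ± 0.17, Oasl1 by 1.47 ± 0.19 and Usp18 by 1.51 ± 0.19. These are targets or regulators of the antiviral type I interferon response. Apol9a, an interferon-induced apolipoprotein L gene, rose by 1.94 ± 0.24, from 7.96 ± 0.46 (SD) in B6 and 7.87 ± 0.35 in IgAkCLM controls to 9.77 ± 0.14 in MupHe and 9.93 ± 0.17 in IgAkMup NASH. The type I interferon list had a median difference of 0.98, with 15 of its 18 members higher over all genes and 17 adjusted over the list alone (camera adjusted p = 1.69e-37, and adjusted p = 0.00281 with an estimated correlation). Within the Tri N libraries its median was 1.41 and 10 members rose, and within the SS N libraries it was 0.85 and 3 rose.

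Other genes higher in NASH included Cdh1, the epithelial cadherin, by 2.00 ± 0.31, Gldn, an adhesion protein of nerve, by 2.09 ± 0.49, Mas1, an angiotensin peptide receptor, by 1.62 ± 0.30, and the stress genes Atf3 (1.74 ± 0.34) and Nupr1 (1.60 ± 0.38). Cyp4a12b, a male-biased P450 gene, rose by 1.90 ± 0.43, the membrane protein gene Tmeff2 by 1.92 ± 0.46 and Ifi27l2b, an interferon-inducible gene, by 1.58 ± 0.39. Lower genes included Lpin1 (-1.78 ± 0.37) and Lpin2 (-0.94 ± 0.20), which make diacylglycerol for triglyceride synthesis. The bile salt and hormone transporter gene Slco1a4 fell by 1.42, the macrophage haemoglobin receptor gene Cd163 by 1.01, the regulator Arid5b by 0.99 and the aminotransferase gene Got1 by 0.89. Herpud1 of the ER stress response (-0.80 ± 0.21), the kinase-dead receptor gene Ephb6 (-0.79 ± 0.16) and Cnmd, a vessel growth inhibitor (-0.75 ± 0.14), were lower as well. The division genes Ccnb2 (0.75 ± 0.16), Cdk1 (0.73 ± 0.17) and Mki67 (0.87 ± 0.22) rose, while Ccnd1 at 1.18 ± 0.33 did not pass (adjusted p = 0.076). Cd8a at 0.36 ± 0.17 (adjusted p = 0.407) and Plau at 0.49 ± 0.38 (adjusted p = 0.649) did not pass. With fewer libraries within a tag, Cdh1, Apol9a, Ifi44 and Oasl1 passed in both tags, Irf7, Usp18, Atf3, Nupr1, Cd163, Cnmd, Ccnb2 and Mki67 only in Tri N, and Ephb6 only in SS N. Gldn, Tmeff2, Cyp4a12b, Mas1, Ifi27l2b, Lpin1, Lpin2, Slco1a4, Arid5b, Got1, Herpud1 and Cdk1 passed in neither. Several differences were larger within Tri N than within SS N: Atf3 stood at 2.68 and 0.81, Nupr1 at 2.32 and 0.88, Ifi27l2b at 2.31 and 0.85, Mki67 at 1.30 and 0.43, Ccnb2 at 1.07 and 0.42, Cd163 at -1.56 and -0.46 and Cnmd at -1.25 and -0.25.

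In NASH, 14 lists passed the test, and only the interferon call held with an estimated correlation. The recruited macrophage list had a median of 0.56, with none of 13 members higher over all genes and 9 adjusted over the list alone (adjusted p = 0.0731 with an estimated correlation). Its members Gpnmb (1.55 ± 0.46) and Trem2 (0.63 ± 0.20) mark lipid-associated macrophages, and neither passed over all genes. Within Tri N and SS N, Gpnmb stood at 2.54 and 0.57 and Trem2 at 1.13 and 0.14. The cholangiocyte list had a median of 0.59 (0 of 11 over all genes, 5 adjusted over the list alone, adjusted p = 0.22 with an estimated correlation), with Cd24a at 1.10 ± 0.33 and Epcam at 0.97 ± 0.34. Within Tri N and SS N the medians were 0.78 and 0.20 for recruited macrophages, 0.64 and 0.55 for cholangiocytes and 0.48 and 0.21 for the cell cycle. The cell cycle list stood at 0.38 (3 of 21 members higher, 7 adjusted over the list alone, adjusted p = 0.213 with an estimated correlation). The urea cycle and amino acid list stood at -0.38 (1 of 18 lower, 4 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation), with Ass1 at -0.61 ± 0.22. Its median was -0.67 within Tri N and -0.11 within SS N.

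The other 9 lists past the test in NASH lost their calls with an estimated correlation, at adjusted p = 0.22 for the male-biased list, 0.277 for B cells, 0.372 for antigen presentation and for p53 targets, 0.504 for the pericentral, oxidative stress and hepatocyte secreted lists, 0.507 for stellate cells and 0.657 for fatty acid synthesis. Their medians were 0.39 for the male-biased list, 0.24 for B cells, 0.15 for antigen presentation, 0.19 for p53 targets, 0.30 for the pericentral list, 0.20 for oxidative stress, -0.16 for the hepatocyte secreted list, 0.22 for stellate cells and -0.30 for fatty acid synthesis. Of their members only Cyp4a12b of the male-biased list passed over all genes, while Col1a1, the main fibre collagen of scar tissue, stood at 0.63 ± 0.31 (adjusted p = 0.418), with 1.26 within Tri N and 0.01 within SS N. The sign of some of these medians differed between tags. Within Tri N and SS N they were 0.54 and -0.14 for p53 targets, 0.43 and -0.0235 for oxidative stress, and -0.04 and 0.73 for the pericentral list. They were 0.38 and 0.03 for stellate cells, 0.21 and 0.59 for the male-biased list, 0.03 and 0.25 for antigen presentation, 0.21 and 0.28 for B cells, -0.30 and -0.08 for the hepatocyte secreted list and -0.52 and -0.04 for fatty acid synthesis. Lists of cholesterol synthesis, lipid droplets and ER stress did not pass in the mean, but passed within Tri N and SS N in opposite directions. Their medians were -0.75 and 0.40 for cholesterol synthesis (adjusted p = 9.27e-11 and 1.37e-05), 0.27 and -0.36 for lipid droplets (0.0292 and 0.0236) and 0.32 and -0.18 for ER stress (0.00382 and 0.0283). The call of the fatty acid synthesis list ended on quantile normalization (adjusted p = 0.3), and that of B cells did too. The fatty acid synthesis call also ended without B6 HFD control 1 (adjusted p = 0.284) and 4 other libraries, and the oxidative stress call without B6 HFD control 2 (0.134), IgAkCLM HFD control 1, MupHe NASH 1 or MupHe NASH 2 (0.121). The hepatocyte secreted call ended without B6 HFD control 1, IgAkCLM HFD control 1, MupHe NASH 2 or IgAkMup NASH 6 (0.0536, 0.0501, 0.0724 and 0.0725), and the p53 call without IgAkCLM HFD control 1 (0.0889).

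In NASH against HFD controls 163 genes passed, 129 higher and 34 lower, and 1504 had an unadjusted p under 0.05. Within the tags 69 genes passed in Tri N and 31 in SS N, 52 and 22 of them shared with the 163, though the mean is made of the same libraries. With weights 719 and 324 passed. The count was 862 (520 higher) in a fit of these groups alone and 1051 (605 higher) with weights per kind of library, so the share of higher genes fell from 79.1% to 57.6%. It was 98 without B6 HFD control 2, 94 without MupHe NASH 1, 101 without MupHe NASH 2 and 83 without IgAkMup NASH 3. Mki67 lost its call in 11 of the 12 fits that leave out a library, Tmeff2 and Got1 in 10, and Herpud1 and Ifi27l2b in 9.

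**Figure D3:**
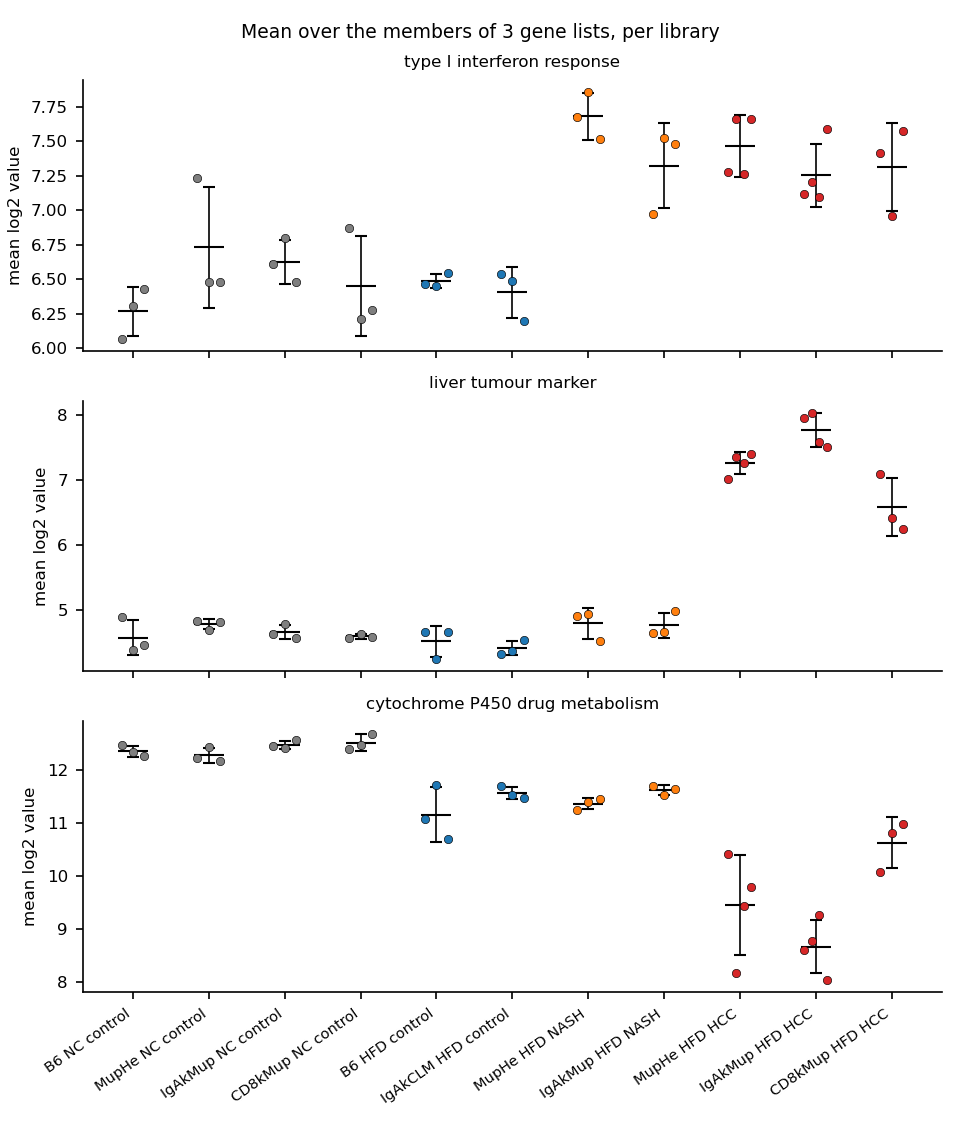
Points are the mean log2 value per library of the members of 3 gene lists (type I interferon response, liver tumour marker and cytochrome P450 drug metabolism), by group, with the group mean and SD. The interferon mean rose from 6.49 in B6 HFD control to 7.68 in MupHe NASH, and the tumour marker mean from 4.79 in MupHe NASH to 7.26 in MupHe HCC.

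Tumours differed from NASH livers by high fetal and tumour genes and by the loss of hepatocyte metabolic genes. Over MupHe and IgAkMup (HCC n = 4 and 4, NASH n = 3 and 3), Apela, a peptide hormone gene of early embryos, rose by 5.04 ± 0.18, from 3.23 ± 0.37 (SD) and 3.43 ± 0.29 in NASH to 8.62 ± 0.50 and 8.11 ± 0.48 in HCC. Spink1, a trypsin inhibitor gene, rose by 5.11 ± 0.53, the cystine transporter gene Slc7a11 by 4.58 ± 0.41, the imprinted fetal RNA H19 by 4.58 ± 1.00 and the oncofetal glypican gene Gpc3 by 4.38 ± 0.65. Cyp2e1, the ethanol-metabolizing P450 gene of pericentral hepatocytes, fell from 15.68 ± 0.29 and 16.06 ± 0.17 to 11.85 ± 1.52 and 10.66 ± 1.51. Cyp4a14, a fatty acid hydroxylase gene, fell by 5.11 and the fatty acid elongase gene Elovl3 by 4.74. In all 5969 genes passed, 3144 higher and 2825 lower.

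Further genes among the largest rises were Cbr3 (4.28 ± 0.26) and Gpx2 (3.77 ± 0.34), targets of the oxidative stress factor NRF2, Rragd, a GTPase of the lysosomal nutrient pathway (4.02 ± 0.21), the kinase gene Styk1 (3.80 ± 0.34) and Lrtm2 (3.60 ± 0.51). Slco1a1, a male-biased transporter gene, fell by 4.54, and Oat, an ornithine aminotransferase gene under Wnt control, stood at -4.47 ± 0.25. The largest falls also held Mup3, Mup11 and Mup17 (-4.72, -4.82 and -4.68), Cyp2c29 and Cyp2c50 (-4.54 and -4.69) and 1 predicted gene, and single members of these families are uncertain. Cd8a stood at 0.58 ± 0.16 (adjusted p = 0.00437), but the exact tests did not pass in MupHe (p = 0.0571, adjusted 0.36) or IgAkMup (p = 0.257, adjusted 0.514). Plau stood at 1.18 ± 0.36 (adjusted p = 0.00708), but did not pass in a fit of the compared groups alone (adjusted p = 0.0722) or in the exact tests (p = 0.457 in MupHe and 0.0571 in IgAkMup).

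Liver metabolism fell broadly in the tumours. In the P450 list 14 of 16 members fell (median -2.04, adjusted p = 0.0632 with an estimated correlation), in the pericentral and Wnt list 15 of 16 (median -2.15, adjusted p = 0.0638 with an estimated correlation), and in the urea cycle and amino acid list 17 of 18 (median -1.14, adjusted p = 0.0972 with an estimated correlation). The bile acid list fell, with 12 of 14 members lower (median -1.61), among them the bile salt uptake transporter gene Slc10a1 (-3.25 ± 0.31) and the sterol hydroxylase gene Cyp27a1 (-1.40 ± 0.11). The male-biased list fell, with 10 of 14 lower (median -2.10). Fatty acid oxidation had 16 of 19 lower and 1 higher (median -0.74, adjusted p = 0.132 with an estimated correlation), with Cpt2, which imports fatty acids into mitochondria, at -0.99 ± 0.10. Of the urea list, the arginine synthesis gene Ass1 fell by 1.67 and the proline oxidase gene Prodh by 1.82.

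Macrophage genes moved apart in the tumours. The Kupffer cell list, of resident liver macrophages, had 8 of 13 members lower and 3 higher (median -1.85, adjusted p = 0.282 with an estimated correlation), with Timd4 at -2.19 ± 0.11, Cd163 at -2.49 ± 0.19 and the scavenger receptor gene Marco at -3.33 ± 0.28. The recruited macrophage list had 12 of 13 higher (median 1.08, adjusted p = 0.0941 with an estimated correlation), with the integrin gene Itgax at 1.69 ± 0.21 and the chemokine receptor gene Cx3cr1 at 2.00 ± 0.25. The antigen presentation list had 15 of 21 higher (median 0.67, adjusted p = 0.147 with an estimated correlation), led by the class II genes Cd74 (2.37 ± 0.20) and H2-Ab1 (2.13 ± 0.21). In the inflammatory list 8 of 11 members rose and 2 fell (median 1.11, adjusted p = 0.132 with an estimated correlation). The adhesion gene Icam1 rose by 1.38 ± 0.12 and Il18 fell by 1.02.

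All 16 tumour markers rose (median 2.71), including Scd2 (3.42 ± 0.35), a desaturase gene, and Golm1 (1.66 ± 0.20), a Golgi protein gene. The oxidative stress list had 14 of 16 higher (median 1.17), with the quinone reductase gene Nqo1 at 2.38 ± 0.13. The cell cycle list had 19 of 21 higher (median 0.75, adjusted p = 0.16 with an estimated correlation), with the kinase gene Plk1 at 1.17 ± 0.15 and the topoisomerase gene Top2a at 1.23 ± 0.20. The stellate cell list had 13 of 17 higher and 1 lower (median 0.74, adjusted p = 0.465 with an estimated correlation), with the basement membrane collagen gene Col4a1 at 2.06 ± 0.15 and Col1a1 at 1.43 ± 0.29. The immediate early list had 7 of 13 higher (median 0.38, adjusted p = 0.176 with an estimated correlation), with Klf6 at 0.99 ± 0.13. The lipid droplet list (median -0.77, 9 of 14 lower and 1 higher, adjusted p = 0.509 with an estimated correlation) and the erythroid list (median -0.59, 5 of 7 lower, adjusted p = 0.502 with an estimated correlation) also passed. The lipid droplet call ended with the stricter filter (adjusted p = 0.102), median centring, quantile normalization (adjusted p = 0.1) and without any of 7 libraries, at most 0.0934 without MupHe HCC 3.

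The interferon list did not pass its test in HCC against NASH (median -0.26, 2 higher and 6 lower of 18, adjusted p = 0.241), and neither did the hepatocyte secreted list (median -0.06, 1 higher and 5 lower of 15, adjusted p = 0.314) or the T cell list (median 0.56, 4 higher and 1 lower of 6, adjusted p = 0.213). Of the 17 lists past the test, those of tumour markers (adjusted p = 0.000105), bile acids (0.013), oxidative stress and male-biased genes (both 0.0432) held with an estimated correlation. Median centring gave 6056 genes, of which 2752 were higher, so the balance of rises and falls rests on the scaling. A fit of these groups alone gave 4309 genes and the weighted fit 5573.

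MupHe and IgAkMup tumours, tested apart, share no libraries and moved largely alike. In MupHe 1972 genes rose and 1812 fell against NASH, and in IgAkMup 2857 rose and 2551 fell. Both lists of risen genes held 1244 genes, with 457 expected by chance, and both lists of fallen genes held 1049, with 375 expected, while 127 genes passed in opposite directions. The differences correlated over 12337 genes with Pearson's r = 0.758 and Spearman's rho = 0.609, across genes, which are not independent replicates. The IgAkMup pair carries the tags SS H and SS N, which share SS, and the MupHe pair SS H and Tri N. Only the IgAkMup pair is therefore matched for SS or Tri. Whether SS H and SS N libraries were handled alike is not known. With the IgAkMup NASH group in place of MupHe NASH, which also changes the genotype, 3607 genes passed in MupHe tumours. In MupHe, Gstp2, a glutathione transferase gene, rose by 4.85 ± 0.52, the ubiquitin-like gene Ubd by 4.75 ± 0.50, the tektin gene Tekt5 by 4.25 ± 0.66 and the hepatokine gene Fgf21 by 2.10 ± 0.37. In IgAkMup, Gpc3 rose by 6.21 ± 0.92, the fetal albumin gene Afp by 4.31 ± 0.70, the peptide gene Apln by 3.99, Igfbp1 by 3.80 and the p53 target Phlda3 by 2.78 ± 0.30. A fit of the compared groups alone gave 1210 genes in MupHe and 3205 in IgAkMup.

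Single genes passed between IgAkMup and MupHe tumours (4 against 4 libraries), and their number rests on the fit. Of 35 splits of these libraries 6, the real one included, gave as many genes, so chance is not excluded for the count. Smo, the transducer of Hedgehog signals, stood at 7.08 ± 0.31 (SD) against 5.32 ± 0.41, a difference of 1.76 ± 0.18 (adjusted p = 1.81e-06, and 0.00387 with weights). Myof, a membrane repair gene, was higher by 1.30 ± 0.18 and the phosphatase gene Ptpn13 by 1.28 ± 0.24. The alanine aminotransferase gene Gpt was lower by -1.63 ± 0.24, the proline oxidase gene Prodh by -1.54 ± 0.25, the P450 gene Cyp2f2 by -2.86 ± 0.44 and the mitochondrial carrier gene Slc25a10 by -1.29 ± 0.19. Zfp462 (1.01 ± 0.16), Serpina3c (1.93 ± 0.37) and Serpina11 (1.48 ± 0.19) were higher. Limk1 (-1.54 ± 0.25), Adh4 (-1.28 ± 0.20), Srd5a1 (-1.27 ± 0.19), Hgd (-0.95 ± 0.15), Fmo5 (-1.52 ± 0.26) and Ehhadh (-1.65 ± 0.31) were lower. These 16 genes also passed with weights.

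The same comparison gave 1249 genes past the threshold, 508 higher and 741 lower, with 3238 at an unadjusted p under 0.05. With weights 83 genes passed (18 higher), which moved the share of higher genes from 40.7% to 21.7%, and none passed in a limma fit of these groups alone, where Smo stood at adjusted p = 0.436. The count was 797 without MupHe HCC 2, 2895 without MupHe HCC 3, 583 without MupHe HCC 4 and 754 without IgAkMup HCC 5. Without the 3 tumours apart on component 2 it was 1993. Sorl1 (1.45 ± 0.29), Pkm (1.18 ± 0.26), Dixdc1 (1.01 ± 0.20), Id1 (1.04 ± 0.29), Gstp2 (-1.85 ± 0.48), Ces1g (-1.40 ± 0.30), Ces1d (-1.22 ± 0.26) and Cth (-1.20 ± 0.29) passed without weights and not with them. Cd8a stood at 0.46 ± 0.21 (adjusted p = 0.172) and Plau at 0.03 ± 0.47.

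Between IgAkMup and MupHe tumours 10 lists passed, and none held with an estimated correlation, where all stood at adjusted p = 0.401. Lower were the urea and amino acid list (median -0.67, 6 of 18, 8 adjusted over the list alone), fatty acid oxidation (-0.50, 7 of 19, 8 adjusted over the list alone), oxidative stress (-0.55, 5 of 16, 8 adjusted over the list alone), P450 (-0.50, 3 of 16, 6 adjusted over the list alone), lipid droplet (-0.55, 3 of 14, 7 adjusted over the list alone) and bile acids (-0.36, 1 of 14). Nqo1 stood at -0.76 ± 0.17, the fatty acid uptake gene Cd36 at -0.87 ± 0.19 and Acadm at -0.68 ± 0.15. Higher were the cholangiocyte list (0.53, 2 of 11), with Prom1 (1.40 ± 0.28) and Spp1 (1.92 ± 0.53), the immediate early list (0.35, 3 of 13), with Socs3 (1.12 ± 0.23) and Fos (0.85 ± 0.20), p53 targets (0.27, 2 of 14) and T cells (0.46, 0 of 6 over all genes, 4 adjusted over the list alone). The T cell call ended without MupHe HCC 2 (adjusted p = 0.0668) or IgAkMup HCC 9 (0.163) and on quantile normalization (adjusted p = 0.0521), and the cholangiocyte call without IgAkMup HCC 5 (0.220) and with the stricter filter (adjusted p = 0.0845). Those of P450 and lipid droplets ended without MupHe HCC 2 (both 0.0668), that of immediate early genes without IgAkMup HCC 7 (0.0608), that of p53 targets without MupHe HCC 2, MupHe HCC 3, IgAkMup HCC 5 or IgAkMup HCC 7 (0.277) and that of bile acids without MupHe HCC 2, 4 or 7 or IgAkMup HCC 7 (0.218) or 8. Without the 3 tumours apart the calls of p53 targets (adjusted p = 0.0519) and oxidative stress (0.111) ended.

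Single genes passed between tumours of libraries labelled CD8kMup (n = 3) and MupHe tumours (n = 4) in the fit of all groups. None passed with weights or in a fit of these groups alone. Of 35 splits of these libraries 11, the real one included, gave as many genes, so chance is not excluded. Cd8a did not differ detectably between these groups, while Cd8b1 stood lower in CD8kMup, at 1.82 against 2.41 (exact p = 0.0286, adjusted 0.36). These genes do not settle whether the label matches the genotype, which limits the meaning of this comparison. Oat stood at 10.93 ± 0.69 (SD) against 8.82 ± 0.94, a difference of 2.11 ± 0.35 (adjusted p = 0.00436, and 0.276 with weights). The lipid transporter gene Mfsd2a was higher by 2.96 ± 0.51, the uridine phosphorylase gene Upp2 by 2.49 ± 0.55, Rgn by 2.09 ± 0.46, the gluconeogenesis gene Pck1 by 1.55 ± 0.39 and Got1 by 1.37 ± 0.30. The macrophage genes Folr2 (1.66 ± 0.34), Fcna (1.65 ± 0.40) and Timd4 (0.81 ± 0.15) were higher. Cyp2c50 (2.45 ± 0.49) and Cyp2c54 (2.00 ± 0.52) were higher, with reads possibly shared. Lower were Gstp2 (-2.73 ± 0.52), Styk1 (-1.92 ± 0.48), Igdcc4 (-1.55 ± 0.40), Apela (-1.25 ± 0.25), Slamf9 (-1.07 ± 0.20), Inhbb (-1.02 ± 0.25), Galns (-1.01 ± 0.22), Col4a1 (-0.97 ± 0.21), Prkcdbp (-0.95 ± 0.20) and Fam84b (-0.95 ± 0.25).

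In all 163 genes passed between CD8kMup and MupHe tumours, 87 higher and 76 lower, with 2004 at an unadjusted p under 0.05. In limma fits with weights, and of these groups alone, 0 genes passed. The count was 370 without MupHe HCC 2, 1088 without MupHe HCC 4, 33 without MupHe HCC 7, 9 without CD8kMup HCC 4 and 9 without CD8kMup HCC 8, and 530 without the tumours apart on component 2. Cyp2e1 at 2.26 ± 0.59 (adjusted p = 0.0517), Clec4f of Kupffer cells at 2.03 ± 0.62 (0.0923) and the fetal growth factor gene Igf2 at -2.74 ± 1.05 (0.177) did not pass.

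Of 14 lists past the test between CD8kMup and MupHe tumours, none held with an estimated correlation. P450 (median 1.01, 4 of 16 members higher, 7 adjusted over the list alone, adjusted p = 0.2 with an estimated correlation), bile acids (0.86, 2 of 14, 0.2), pericentral genes (0.75, 1 of 16, 0.205), Kupffer cells (0.49, 2 of 13, 0.205), urea and amino acids (0.60, 1 of 18, 0.22) and male-biased genes (0.48, 1 of 14, 0.261) were higher. So were the erythroid (0.76), female-biased (1.10) and ER stress (0.42) lists, all at adjusted p = 0.275 with an estimated correlation, fatty acid oxidation (0.20, 0.551) and fatty acid synthesis (0.43, 0.74). Tumour markers (-0.66, 0.2), cell cycle (-0.26, 0.551) and oxidative stress (-0.39, 0.307) were lower. In these 8 lists no member passed over all genes. Without the tumours apart on component 2 the calls of tumour markers (adjusted p = 0.0923), female-biased genes (0.172), fatty acid synthesis (0.353) and fatty acid oxidation (0.953) ended. Single libraries also ended calls: the male-biased call without CD8kMup HCC 4 (0.0513), that of cell cycle without MupHe HCC 4 (0.151) or CD8kMup HCC 4, that of oxidative stress without MupHe HCC 7 (0.0713), that of tumour markers without CD8kMup HCC 8 (0.132), CD8kMup HCC 4, MupHe HCC 3 or MupHe HCC 4, that of female-biased genes without MupHe HCC 3 (0.178) or CD8kMup HCC 8 (0.123), that of fatty acid oxidation without MupHe HCC 3 (0.960) or CD8kMup HCC 8 (0.0851) and that of fatty acid synthesis without any of 5 libraries (0.0655 to 0.685, the latter without CD8kMup HCC 8).

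The step from NASH to HCC was tested for a difference between IgAkMup and MupHe. It differed in 1236 genes, 595 more positive in IgAkMup and 641 more negative, with 932 in the weighted fit and 13 in a fit of these groups alone. The amino acid genes Hgd (-1.38 ± 0.23) and Prodh (-1.68 ± 0.39) and the P450 gene Cyp2f2 (-2.83 ± 0.67) were more negative in IgAkMup. Nqo1 (-1.11 ± 0.27), Ubd (-2.94 ± 0.71) and Gstp2 (-2.71 ± 0.74) rose less, and Serpina3c stood at -3.90 ± 0.56. The sphingosine phosphatase gene Sgpp2 (3.10 ± 0.73), Myo5c (2.47 ± 0.65), the serine synthesis gene Phgdh (2.16 ± 0.66) and the antibody joining chain gene Jchain (2.38 ± 0.70) were more positive, as were the nuclear RNAs Malat1 (3.08 ± 0.46) and Neat1 (2.81 ± 0.52). The NASH groups carry different tags, so the tag is part of this difference. The count was 2440 without MupHe HCC 3, 656 without MupHe NASH 2, 528 without IgAkMup NASH 2 and 759 without IgAkMup NASH 3.

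For that step 6 lists passed, all more negative in IgAkMup, and none held with an estimated correlation (all adjusted p = 0.93). They were urea and amino acids (median -0.85, 5 of 18, 8 adjusted over the list alone), P450 (-0.82, 2 of 16), oxidative stress (-0.65, 1 of 16), cholesterol synthesis (-0.53, 0 of 22), antigen presentation (-0.48, 2 of 21 and 1 more positive) and fatty acid oxidation (-0.42, 2 of 19, 5 adjusted over the list alone). The P450 and fatty acid oxidation calls ended without MupHe HCC 2 (adjusted p = 0.0747 and 0.0560), that of cholesterol synthesis without any of 6 libraries (at most 0.280 without IgAkMup HCC 5) and that of antigen presentation without any of 5 (at most 0.104 without MupHe HCC 3).

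In healthy livers of the NC groups few genes passed between genotypes in the fit of all groups (n = 3 per group). MupHe against B6 differed in 6 genes. The cell cycle inhibitor gene Cdkn2c rose by 1.37 ± 0.17, from 5.00 ± 0.34 (SD) to 6.37 ± 0.03 (adjusted p = 7.61e-05). The necroptosis gene Mlkl rose by 1.13 ± 0.22 and the urinary protein genes Mup9 and Mup8 by 3.95 ± 0.71 and 1.24 ± 0.21, while the protease inhibitor gene Serpine2 fell by 2.21. Oasl1 (0.98 ± 0.26), Gpnmb (2.00 ± 0.65) and Atf3 (2.05 ± 0.48) did not pass. In all, 648 genes had an unadjusted p under 0.05, close to a share of 0.05 of the kept genes. This count does not tell a difference from chance. The fit shares its spread with the more variable tumour groups, and simulated data with measured spread gave 0 false among 133 calls here. The count was 94 in a fit of these groups alone, 172 with weights, 20 without a filter and 3 on quantile normalization, and the share of higher genes was 83.3% and with weights 69.8%. It was 1 without B6 NC 1, without B6 NC 3, without MupHe NC 1 and without MupHe NC 3.

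Between MupHe and B6 NC livers 10 lists passed and none held with an estimated correlation, and no member passed over all genes. The recruited macrophage list stood at 0.63 (2 adjusted over the list alone, adjusted p = 0.135 with an estimated correlation), the cholangiocyte list at 0.45 (0.55), the interferon list at 0.40 (2 adjusted over the list alone, 0.342), stellate cells at 0.38 (0.55), ER stress at 0.34 (0.493), Kupffer cells at 0.33 (0.55) and inflammatory genes at 0.28 (0.233). The p53 list stood at 0.19 (0.55), antigen presentation at 0.16 (0.55) and fatty acid oxidation at -0.24 (0.493). The calls of Kupffer cells and antigen presentation ended without B6 NC 1 (adjusted p = 0.269 and 0.446) or MupHe NC 1 (0.232 and 0.183), that of cholangiocytes without B6 NC 1 or MupHe NC 2 (0.114), that of p53 targets without B6 NC 2 or MupHe NC 1 (0.124) and that of inflammatory genes without B6 NC 3 (0.0600).

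IgAkMup against MupHe NC livers differed in 2 genes, with 437 at an unadjusted p under 0.05. That is fewer than a share of 0.05 of the kept genes, but simulated data with measured spread gave 0 false among 134 calls here. The count therefore does not tell a difference from chance. Serpina3c, a serine protease inhibitor gene, stood at 9.50 ± 0.39 (SD) against 3.67 ± 0.21, a difference of 5.83 ± 0.42 (adjusted p = 6.85e-10), and Mup8 at -1.33 ± 0.21 (adjusted p = 0.00612). Reads of both families may be shared between paralogs. The count was 200 in a fit of these groups alone, 12 with weights, 4 without a filter and 1 with the stricter filter. It was 1 without MupHe NC 1, without IgAkMup NC 2 and without IgAkMup NC 3. Cyp4a14 at 3.12 ± 0.73 (adjusted p = 0.411) and Cd163 at 1.03 ± 0.29 (0.728) did not pass. Of 10 lists past the test none held with an estimated correlation, and their medians lay between -0.42 for the male-biased list (adjusted p = 0.469) and 0.76 for the female-biased list (0.469), with lipid droplets at 0.31 (0.469), Kupffer cells at 0.32 (0.469) and fatty acid oxidation at 0.18 (0.469). The male-biased call ended without IgAkMup NC 2 (adjusted p = 0.113) and that of Kupffer cells without MupHe NC 2 (0.209). That of antigen presentation ended without IgAkMup NC 2 or MupHe NC 3 (0.0782 and 0.186). That of cholesterol synthesis ended without IgAkMup NC 2 or 3 or MupHe NC 1 or 3 (0.107 to 0.285).

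Libraries labelled CD8kMup NC against MupHe NC differed in 2 genes, Mup18 (-2.07 ± 0.37) and Mup8 (-1.19 ± 0.21), both at adjusted p = 0.0382 and from a family of near-identical genes. The open question about this label applies here too, with Cd8a not detectably different and Cd8b1 at 1.81 against 2.03 (exact p = 0.2). At an unadjusted p under 0.05 there were 367, fewer than a share of 0.05 of the kept genes. Simulated data with measured spread gave 0 false among 137 calls here, so this count does not tell a difference from chance either. A fit of these groups alone gave 26 other genes and ended both calls (adjusted p = 0.0648 for Mup18 and 0.122 for Mup8). With weights the count was 17, of which 29.4% were higher, and limma gave 0 without a filter, with the stricter filter and on quantile normalization. It was 0 without MupHe NC 1, 2 or 3 and without CD8kMup NC 2 or 3, and 10 without CD8kMup NC 1. The cell cycle list stood at 0.38 (adjusted p = 0.438 with an estimated correlation), fatty acid oxidation at 0.19 and the interferon list at -0.29 (both 0.868), and the last 2 calls ended without MupHe NC 1 (adjusted p = 0.0512 and 0.732).

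With the replicate number in the sample titles of the NC groups as a block, 3 genes passed for MupHe against B6, 2 for IgAkMup against MupHe and 2 for CD8kMup against MupHe. The column names of some IgAkMup and CD8kMup NC libraries end in other numbers, and those were not tried. Correlations of the residual profiles of libraries with the same number ran from -0.212 to 0.226 (18 pairs, median 0.0197), and those with other numbers from -0.278 to 0.244 (36 pairs). Libraries did not correlate best with their own number throughout, so the number gave no hint of pairs. No paired analysis was possible for the HFD-fed groups because their columns match a group and not a sample.

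Fatty livers of IgAkCLM and B6 on the high-fat diet, and NASH livers of IgAkMup and MupHe, were compared across library tags, so both the genotype and the tag enter each difference. IgAkCLM against B6 HFD controls differed in 637 genes (459 higher). Serpina3c was higher by 6.37 ± 0.42, Neat1 by 2.54 ± 0.39, Malat1 by 2.28 ± 0.35 and the cholesterol synthesis gene Sqle by 2.02 ± 0.57. The p53 target and cell cycle inhibitor gene Cdkn1a was lower by -2.25 ± 0.38, the stress hormone gene Gdf15 by -1.65 ± 0.35, the detoxification gene Gsta1 by -2.27 ± 0.42, Anxa2 by -1.57 ± 0.24 and the mitochondrial transhydrogenase gene Nnt by -1.54 ± 0.18. The weighted count was 1863, with 57.5% higher against 72.1%. It was 345 without B6 HFD control 1, 180 without B6 HFD control 3, 215 without IgAkCLM HFD control 1 and 283 without IgAkCLM HFD control 2. Of 13 lists past the test none held with an estimated correlation, among them cholesterol synthesis (0.73, adjusted p = 0.582) and p53 targets (-0.58, adjusted p = 0.113).

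IgAkMup against MupHe NASH differed in 372 genes, 70 higher and 302 lower. Serpina3c was higher by 5.83 ± 0.42, Serpina11 by 1.35 ± 0.22, the inflammasome cytokine gene Il18 by 0.80 ± 0.19 and the polyamine oxidase gene Paox by 0.92. Neat1 (-2.69 ± 0.39), Malat1 (-2.14 ± 0.35), Firre (-2.07), Leng8 (-1.73) and the nicotinamide methyltransferase gene Nnmt (-1.97) were lower. A fit of these groups alone gave 1047 genes and the weighted fit 2210, of which 47.4% were higher against 18.8%. The count was 173 without MupHe NASH 1, 136 without MupHe NASH 2, 185 without MupHe NASH 6, 112 without IgAkMup NASH 2 and 131 without IgAkMup NASH 3. The lists of antigen presentation (0.42), cholesterol synthesis (0.46) and interferon (-0.33) passed without a member past the threshold, and all stood at adjusted p = 0.994 with an estimated correlation. The interferon call ended without MupHe NASH 2 or IgAkMup NASH 2 (adjusted p = 0.0510 and 0.414).

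NASH against HFD controls was also tested for each NASH genotype apart, again across tags. Each control has another genotype than its NASH group, so stage and genotype cannot be told apart here. MupHe NASH against B6 differed in 637 genes (410 higher), with Ifi44 at 1.89 ± 0.32, Apol9a at 1.81, Oasl1 at 1.71 and Ddx60, a helper of RNA sensing, at 1.71, and Chac1 (-1.44), Herpud1 (-1.47) and Lpin2 (-1.18) lower. Neat1 stood at 2.63 ± 0.39 and Malat1 at 2.25 ± 0.35, but Malat1 at -0.03 against the IgAkCLM control of the same tag. Against that control, which also differs in genotype, 69 genes passed (719 with weights), 28 of the 69 shared, with the MupHe NASH libraries in both comparisons. The count was 308 on quantile normalization, 1084 in a fit of these groups alone and 2320 with weights (49.2% higher against 64.4%). It was 272 without B6 HFD control 1, 245 without B6 HFD control 3, 262 without MupHe NASH 1 and 191 without MupHe NASH 2. The interferon list stood at 1.18, with 12 of 18 members higher and 18 adjusted over the list alone (adjusted p = 0.0749 with an estimated correlation). The urea list at -0.36 and the pericentral list at 0.57 passed as well (both adjusted p = 0.927 with an estimated correlation), the latter at -0.04 against the control of the same tag. Their calls ended without B6 HFD control 3 (adjusted p = 0.0541 and 0.0874), and that of the urea list also without B6 HFD control 2 (0.0513).

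IgAkMup NASH against IgAkCLM, a comparison added later, also crosses tags and differed in 1068 genes (391 higher). Against the B6 control of its own SS N tag 31 genes passed, and 324 with weights. Its interferon list stood at 1.03 with 9 of 18 members higher (adjusted p = 0.279 with an estimated correlation), and at 0.85 with 3 higher against B6. The count was 2712 in a fit of these groups alone and 3032 with weights (48.2% higher against 36.6%), and 486 without IgAkCLM HFD control 1, 539 without IgAkCLM HFD control 2, 488 without IgAkMup NASH 2 and 371 without IgAkMup NASH 3.

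Fatty livers of B6 on the high-fat diet differed from healthy B6 livers of the NC group (n = 3 each) in 2538 genes, 1183 higher and 1355 lower. These groups carry the tags SS N and Tri NC, so values with the Tri N IgAkCLM HFD control in place of the B6 one (with Tri libraries) stand beside them. Those share Tri with the NC group but not the second part of the tag, and also change the genotype of the HFD group. The labels do not explain NC, and the processing notes of NC and HFD-fed samples differ. Diet, tag and processing therefore cannot be told apart in either form. The fatty acid uptake gene Cd36 rose by 2.34 ± 0.22 (1.45 ± 0.22 with Tri libraries), the pantetheinase gene Vnn1 by 2.44 ± 0.36 (1.79 ± 0.36), the peroxisomal oxidase gene Hao2 by 2.79 ± 0.47 (1.99), the repair gene Rad51b by 3.65 ± 0.42 (2.54), the female-biased P450 gene Cyp2b9 by 4.79 ± 1.05 (4.52 ± 1.05) and the signalling gene Rgs16 by 3.28 ± 0.96 (4.03), each past the threshold in both. Mup7 fell by 5.57 (-4.46), Selenbp2 by 3.91 (-3.47) and Serpina1e by 4.11 (-3.70), likewise in both. Cdkn1a rose by 3.37 ± 0.38, but stood at 1.12 with Tri libraries (adjusted p = 0.129), and the male-biased steroid gene Hsd3b5 fell by 5.09, but stood at -2.50 (adjusted p = 0.0534). With Tri libraries 285 genes passed (1360 with weights), 239 of the 285 shared in the same direction. Both forms use the same B6 NC libraries, so they are not independent and some sharing follows from that.

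Lipid and sex-biased liver lists changed in both forms of the comparison of HFD with NC. Past the test with either HFD group were the female-biased list (median 2.76, and 1.99 with Tri libraries, adjusted p = 0.25 with an estimated correlation), male-biased list (-1.62 and -1.17, 0.146), lipid droplets (1.01 and 0.52, 0.25), fatty acid oxidation (0.74 and 0.50, 0.24), P450 (-1.27 and -0.75, 0.332) and antigen presentation (0.42 and 0.29, 0.442). Of 16 lists past the test none held with an estimated correlation. The calls of the other 10 ended with Tri libraries, among them p53 targets (0.83, adjusted p = 0.827), cholesterol synthesis (-0.96, 0.387) and ER stress (0.56, 0.677). The count was 4550 with weights, where simulated data gave 33 false among 190 calls, and 1558 without B6 HFD control 3 and 1583 without B6 NC 1.

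**Figure D4:**
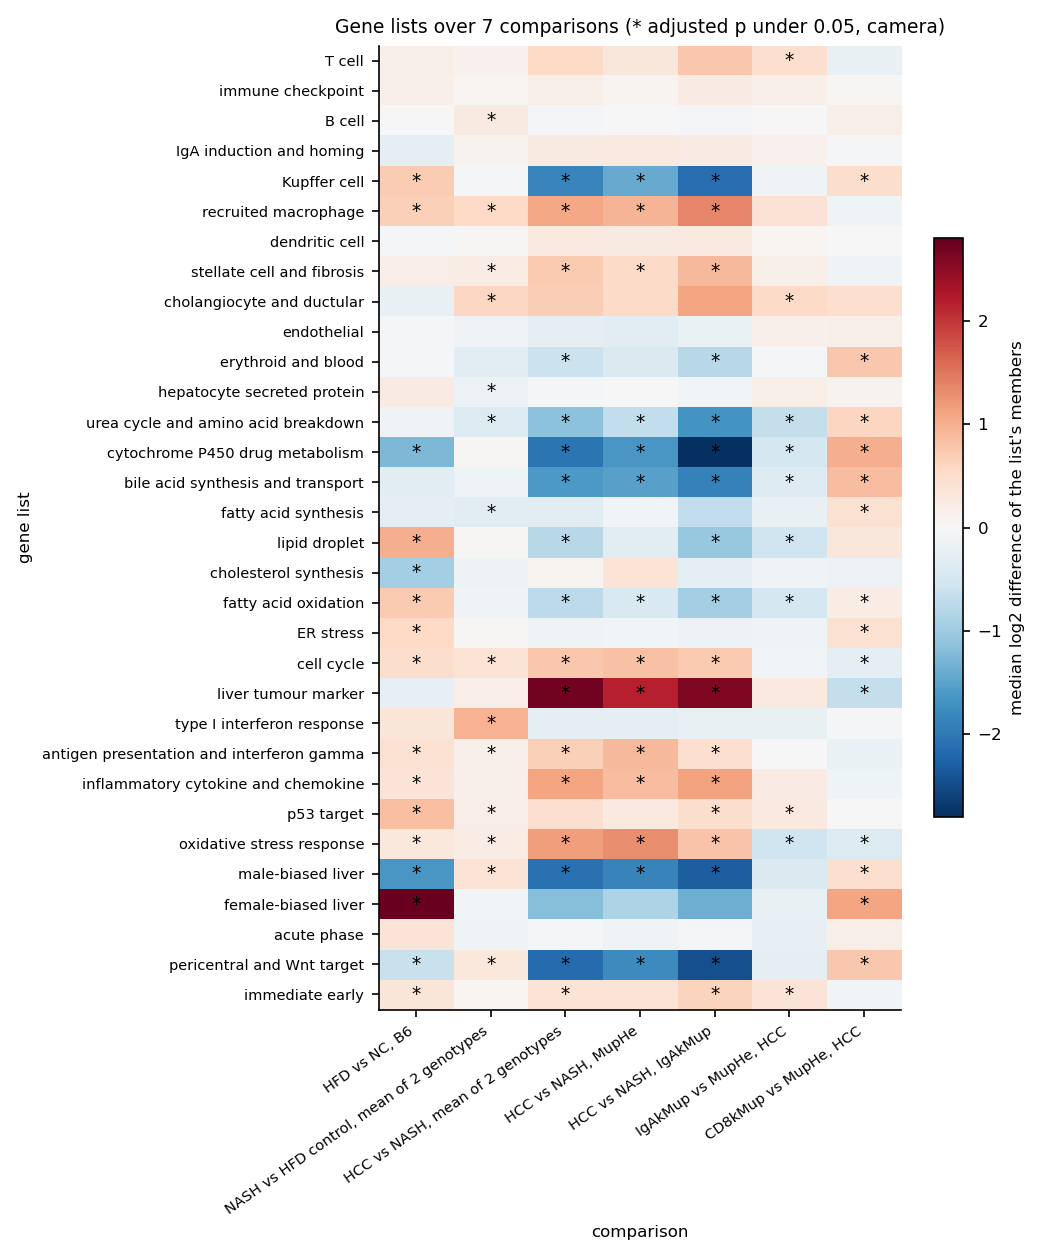
Colours give the median log2 difference of the members of 32 gene lists in 7 comparisons, and a star marks a camera adjusted p under 0.05 at the preset correlation. The P450 list stood at -2.04 in HCC against NASH and at 1.01 in CD8kMup against MupHe HCC.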

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

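Of the tests in this part, the comparison of the NASH and HFD control contrasts between genotypes was chosen only after the column tags were seen.

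In the groups of 4 libraries, 191 values were tested for a library far from the rest, and 13 stood out. About 1 in 20 would by chance, which is near this share, and genes of a library are not independent. Higher values in MupHe HCC 2 were Cyp4a14 at 11.073 (the others 7.46 to 7.59), Cyp2c50 at 9.2175 (7.13 to 7.45) and Cyp2c54 at 7.5142 (5.60 to 5.89). Its Serpina3c, at 2.817 (2.96 to 2.99), was slightly lower. MupHe HCC 3 was low in the uridine phosphorylase gene Upp2 at 5.6562 (7.24 to 7.54), in BC089597 at 5.8356 (7.41 to 7.57) and in the carboxylesterase gene Ces1f at 9.1232 (11.03 to 11.30). MupHe HCC 4 was high in the cysteine synthesis gene Cth at 12.123 (10.5 to 10.8). In IgAkMup HCC 7 the BMP target Id1 was high at 7.2636 (6.69 to 6.72) and Ces1g low at 9.5944 (11.3 to 11.5). In IgAkMup HCC 8 Gstp2 was low at 4.5137 (7.47 to 7.97) and the mean of the recruited macrophage list high at 7.5137 (6.77 to 6.86). In IgAkMup HCC 5 the mean of the cholangiocyte list was high at 7.9142 (6.24 to 6.33).

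The difference between HCC and NASH itself differed between IgAkMup and MupHe in 1236 genes, by an interaction test in limma. The 2 NASH groups carry different tags, so this genotype difference of the HCC step holds the tag too. The NASH contrasts, IgAkMup NASH minus IgAkCLM and MupHe NASH minus B6, differed from each other in 1615 genes. Of these 635 were more positive for IgAkMup, 39.3% against 50.1% in the weighted fit. IgAkMup and MupHe have no HFD control of their own, so the genotypes of the controls enter too. The count of 1615 equals the split of the same libraries by tag, since it sets SS N libraries against Tri N libraries in both stages. It was 992 without B6 HFD control 3, 1027 without MupHe NASH 2 and 976 without IgAkMup NASH 2. For that contrast 7 lists passed, all more positive in IgAkMup, and none held with an estimated correlation (adjusted p = 0.917 each).

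Genes that differ between SS N and Tri N libraries may follow the tag rather than the genotype. Over 12337 genes, the SS N minus Tri N differences of the HFD controls and of NASH correlated with Pearson's r = 0.394 and Spearman's rho = 0.464, where a share of 0.02 of 400 relabellings gave as large an r, and genes are not independent replicates. Of 217 genes past the threshold in both, 212 had the same SS N minus Tri N direction and 5 the same direction for IgAk, with 19.2 expected in both by chance. The IgAk differences are these same differences with a sign turned, so their correlation of -0.394 is not a second test. A shared IgAk effect larger than that of the tag would make it positive, and a smaller one is not excluded. The nuclear RNAs Malat1 (8.88 ± 0.85 and 8.99 ± 0.62 in SS N, 11.16 and 11.13 in Tri N) and Neat1 (7.34 and 7.28 against 9.88 and 9.97) show it. In the Tri NC groups Malat1 stood at 10.75 to 11.12 and Neat1 at 9.05 to 10.1. In the SS H groups, which are tumours, they stood at 9.54 to 10.56 and 8.51 to 9.33. Serpina3c and Serpina11 followed IgAk and stay open as genotype effects, though Serpina11 did not pass between IgAkMup and MupHe NC.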

How the results depend on the processing

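Weights per kind of library, groups exchanged for ones of the same or a related tag and the omission of 3 tumour libraries were chosen after the data were seen. Median centring, no trend and robust eBayes left all 16 counts of genes near their values. Where a count or direction changed and no cause is named, the cause was not tested.

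In fits of only the compared groups, NASH against HFD control over both genotypes gave 862 genes, MupHe NASH against B6 1084, IgAkMup against MupHe NASH 1047, and IgAkMup NASH against IgAkCLM 2712. The difference of the NASH contrasts, which is the split by tag, gave 3191. MupHe HCC against NASH gave 1210, IgAkMup HCC against NASH 3205, the genotype difference of the HCC step 13, IgAkMup against MupHe HCC 0 and CD8kMup against MupHe HCC 0, where limma gave 3238 and 2004 genes at an unadjusted p under 0.05 with all groups. In NC, MupHe against B6 gave 94, IgAkMup against MupHe 200 and CD8kMup against MupHe 26. The cause was not tested.

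With weights per kind of library the counts were 1051 for NASH over both genotypes, 2320 for MupHe NASH against B6 and 2210 for IgAkMup against MupHe NASH. They were 3032 for IgAkMup NASH against IgAkCLM, 3646 for the difference of the NASH contrasts, 1863 for IgAkCLM against B6 and 4550 for HFD against NC. They were 83 for IgAkMup against MupHe HCC, 0 for CD8kMup against MupHe HCC, and 172, 12 and 17 for MupHe, IgAkMup and CD8kMup in NC. Without the 3 tumours apart on component 2 the counts were 1993 for IgAkMup and 530 for CD8kMup against MupHe HCC, and 2128 for the genotype difference of the HCC step.

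Quantile normalization gave 308 genes for MupHe NASH against B6, 3 for MupHe against B6 NC and 0 for CD8kMup against MupHe NC, and the cause was not tested. In the same 3 NC comparisons no filter gave 20, 4 (IgAkMup) and 0 (CD8kMup), and the stricter filter gave 1 for IgAkMup and 0 for CD8kMup. The replicate block gave 3 for MupHe against B6 NC. With the IgAkCLM control of the same Tri N tag, MupHe NASH gave 69 genes. With the IgAkCLM HFD group (Tri N) in place of B6, HFD against NC (Tri NC) gave 285. Both exchanges change genotype and tag at once.

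Directions reversed in few cases. With quantile normalization the median of the hepatocyte secreted list in NASH became 0.0248. With the IgAkCLM control, MupHe NASH stood at -0.0420 for the pericentral list, -0.0335 for Malat1, -0.19 for Firre and -0.13 for Leng8. With the IgAkCLM HFD group, HFD against NC stood at -0.0126 for the oxidative stress list, -0.12 for Cdk1 and 0.35 for Nlrc5. The fatty acid synthesis list of CD8kMup against MupHe HCC ran from -0.0136 without CD8kMup HCC 8 to 1.01 without CD8kMup HCC 3. The cause was not tested.

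Leaving out 1 library at a time, counts ran from 83 to 187 for NASH over both genotypes and 191 to 564 for MupHe NASH against B6. They ran from 371 to 1024 for IgAkMup NASH against IgAkCLM, 112 to 529 for IgAkMup against MupHe NASH, and 976 to 1803 for the difference of the NASH contrasts. They ran from 5374 to 6238 for HCC over both genotypes, 2565 to 4027 in MupHe and 4185 to 5467 in IgAkMup, and 528 to 2440 for the genotype difference of the HCC step. They ran from 583 to 2895 for IgAkMup and 9 to 1088 for CD8kMup against MupHe HCC, 180 to 782 for IgAkCLM against B6, and 1558 to 2387 for HFD against NC. In NC they ran from 1 to 6 for MupHe against B6, 1 to 2 for IgAkMup and 0 to 10 for CD8kMup against MupHe.

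Of 922 gene results, 921 kept direction and call with robust eBayes, 917 without trend, 897 on median centring, 846 on quantile normalization and 684 in fits of the compared groups. Of 169 list calls, 10 held with an estimated correlation and 97 with fry. Fry kept 17 of 17 calls for HCC against NASH, 14 of 14 in MupHe, 18 of 18 in IgAkMup and 10 of 10 for IgAkMup against MupHe HCC. It kept 15 of 16 for HFD against NC, 6 of 14 for CD8kMup against MupHe HCC and 5 of 13 for IgAkCLM against B6. For NASH it kept 3 of 14 in the mean, 1 of 3 in MupHe and 8 of 11 in IgAkMup. In NC, for IgAkMup against MupHe NASH and for both differences of contrasts it kept 0. Depth is unknown, so what it limits cannot be stated.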

Other observations

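Of the tests in this part, that of non-hepatocyte cells of every kind was chosen after its result was seen, and so were the splits of the added comparisons.

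Too few genes of 6 lists were kept for a test, and their genes are given singly for HCC against NASH over both genotypes. Of cytotoxic lymphocyte genes, Nkg7 rose by 0.38 ± 0.12 (limma adjusted p = 0.0128) and the chemokine gene Ccl5 by 0.59 ± 0.20 (0.0164), while Klrk1 stood at -0.20. The costimulator gene Icos, of the regulatory T cell list, stood at -0.08. Of plasma cell genes the folding gene Fkbp11 rose by 1.53 ± 0.16 (9.71e-09) and the regulator Prdm1 by 0.84 ± 0.12 (3.02e-06), while Jchain (0.44) and Derl3 (-0.42) did not pass. Jchain stood at -0.75 ± 0.49 in MupHe (0.26) and rose by 1.63 ± 0.49 in IgAkMup (0.00916), a difference between genotypes of 2.38 ± 0.70 that passed (0.029). Of neutrophil genes the receptor gene Csf3r rose by 0.48 ± 0.11 (0.000846), and S100a8 (0.14) and S100a9 (0.20) did not pass. Of adipocyte genes Cfd fell by 2.37, Cidea by 1.98 and Plin4 by 1.75, with Adrb3 at -0.55, and the muscle gene Mylpf stood at 0.11. In NASH against HFD control none of these genes passed, with Fkbp11 at 0.62, Derl3 at 1.54 and Jchain at 1.25 (adjusted p = 0.0644, 0.0734 and 0.106). In IgAkMup against MupHe HCC, Jchain stood at 2.04 ± 0.46 and S100a9 at 0.60 ± 0.17.

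Serpina3c followed the IgAk names outside tumours. It stood at 9.50 ± 0.39 (SD) in IgAkMup NC, 9.62 ± 0.63 in IgAkCLM HFD control and 9.06 ± 0.06 in IgAkMup NASH, but at 4.87 ± 1.34 in IgAkMup HCC, and at 2.94 to 3.86 in the other groups. Serpina11 stood at 9.60 to 10.26 on average in the groups named IgAk and at 8.25 to 9.20 in the others. Between the NC groups, which share a tag, it stood at 9.60 in IgAkMup and 9.04 in MupHe and did not pass. Single libraries overlapped, with IgAkMup NC 2 at 9.3415 and B6 HFD control 2 at 9.3441. Nnt, part of which is deleted in C57BL/6J mice, stood highest in B6 HFD control (10.72 ± 0.13) and B6 NC (10.06 ± 0.04) and lowest in CD8kMup NC (8.74 ± 0.18) and IgAkMup NC (8.84). Xist, the RNA of the inactive X chromosome, stood at 2.19 to 2.99 in the 6 SS N libraries and at 1.65 to 1.83 in the 29 others, while the mean of 4 Y-linked genes stood at 7.21 to 7.78 and 7.14 to 8.34. The median SD of a gene was 0.297 in MupHe HCC, 0.261 in IgAkMup HCC and 0.157 in CD8kMup HCC, against 0.109 to 0.157 in the groups without tumours, a ratio of 2.30 for the first 2 tumour groups.

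The fall of hepatocyte metabolic genes in HCC may reflect fewer hepatocytes, more cells of other kinds, or lower expression in the tumour cells. Fewer hepatocytes would lower the secreted protein list about as far as the P450 list. Its median was -0.0585, against -2.04 for the P450 list, and the gap to 50% of the P450 median was 0.961 (0.335 to 1.94, a 95% interval over 10000 resamples of members). More cells of every other kind would raise all their lists, but the Kupffer cell list stood at -1.85 and the recruited macrophage list at 1.08. These lists speak only against a rise of every kind, by a test chosen after the result was seen. A rise of some kinds, such as recruited macrophages, stays open, and so does a lower expression in tumour cells. Neither was tested.

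Serpina3c and Serpina11 lie on chromosome 12 (from 104146382 and 103980243), near Igha (from 113254830), so DNA carried along with a targeted Igha locus may underlie their difference. With both left out, 2 of 122 genes within 15 Mb of Igha (1.64%) and 101 of 11957 other genes (0.845%) had an unadjusted limma p under 0.01 between IgAkMup and MupHe NC (one-sided Fisher's exact p = 0.279). The shares were 9.84% and 9.55% for IgAkCLM against B6 (exact p = 0.503), 8.20% and 6.83% in NASH (0.324) and 6.56% and 13.6% in HCC (0.995). With so few genes near the locus a carried stretch and an effect of genotype cannot be told apart, and a difference in strain background stays open.

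The same libraries were split otherwise to see how many genes other groupings give. The real grouping gave the most genes for HCC against NASH over both genotypes (5969, the highest other 4548), in MupHe (3784 and 3088) and in IgAkMup (5408 and 4208). It also did for the genotype difference of the HCC step (1236 and 1031). The same held for the difference of the NASH contrasts (1615 and 466), which is the split by tag and not a genotype result. In each of these only 1 split, the real one, gave as many. That is a share of 0.01 of 100 splits, or of 0.0286 of 35, the smallest that these numbers of splits can give. The shares were not adjusted over the 16 comparisons, so chance is less likely by this count but not excluded. For NASH over both genotypes 5 of the 100 splits drawn, the real one included, gave as many (163, the highest other drawn 516). For IgAkMup against MupHe HCC 6 of 35 did (1249 and 3340), and for CD8kMup against MupHe HCC 11 of 35 (163 and 1543). In the NASH comparison other splits can set SS N against Tri N libraries unevenly, unlike the real one. That share therefore cannot tell chance from the tag. Splits that call several times the real count may point to a structure among the tumours other than genotype, or to the raised error rate that unequal spread gave on simulated data (655 false among 815 calls), and no test separated these. Among the 12 NASH and HFD control libraries the split by tag gave 1615 genes and the split by stage 163.

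With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. There the real and highest other counts were 637 and 0 for MupHe NASH against B6, 372 and 0 for IgAkMup against MupHe NASH, 637 and 1 for IgAkCLM against B6, 1068 and 0 for IgAkMup NASH against IgAkCLM, and 2538 and 1 for HFD against NC. In NC they were 6 and 0 for MupHe against B6, 2 and 0 for IgAkMup and 2 and 0 for CD8kMup against MupHe.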
